A study of Homo sapiens with 36 samples.

How the data were processed

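The deposited files hold raw counts per gene, given by the authors as fragments assigned by featureCounts 2.0.1 to the exons of each gene name, per the file headers, without regard to strand. The annotation was GENCODE release 41 on hg38. Reads were trimmed with cutadapt and Trim Galore, aligned with STAR and handled with SAMtools, per the submitters' processing notes; no versions were given there. Each file held 60606 gene rows. Fragments mapping to several places or to exons of more than 1 gene were not counted, which concerns all exon bases of 2176 rows, 86 of them among 19368 protein-coding genes; 117 of these rows still held counts. Gene types came from GENCODE release 29 and RefSeq and were found for 40075 rows. Named genes with a large share of exon bases lost this way, whose levels are less certain, were CCDC152 (41.6%), FOXH1 (39.2%), LEFTY1 (46.6%), MRPL12 (69.5%), NODAL (33.5%), PCDHAC2 (46.9%), PCDHGA10 (32.8%), PEG3 (50.9%) and VIPR2 (39.4%).

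Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr (count 10, total 15). Libraries were scaled by TMM, and CPM levels are TMM-scaled except where CPM of all assigned fragments is stated. Quasi-likelihood F-tests with robust dispersion were adjusted by Benjamini-Hochberg within each comparison, threshold 0.05. The 20 comparisons came from 4 fits: hPGCLC (14 libraries, 7 residual degrees of freedom, biological coefficient of variation 0.163), hESC (16, 8, 0.0997), the controls of 5 cell types (10, 5, 0.202), and hPGCLC with hESC for the differences between cell types (30, 15, 0.130). No batch is labelled, so none was modelled.

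The 22 gene lists were fixed before the data were examined, as were the comparisons, thresholds, naming rules and first set of alternatives: amnion and trophoblast, CCR4-NOT deadenylation, cytosolic ribosomal protein, ectoderm, endoderm, fibroblast, G1 and S phase, G2 and M phase, germ cell specification, HOX, hypoxia and glycolysis, integrated stress response, interferon response, later germ cell, mesoderm, mitochondrially encoded, p53 target, pluripotency, processing body, replication-dependent histone, signalling response and SOX transcription factors. Each was tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the libraries. Member counts adjusted over the list alone used the p-values of the members only. Named in every comparison were DND1, NANOS3 and SOX4, and ADAR where a line carried it. Beyond these, genes were named for the largest fold change among those past the threshold, with at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups, 10 per direction in the 3 hPGCLC knockout comparisons and 5 elsewhere. Unnamed loci, antisense and pseudogene symbols and genes of the sex chromosomes used for sexing were left out. From a list with 3 members past the threshold or a set past it, up to 4 members with the largest change were eligible. Some genes that met these rules are not reported here. Where a group had 0 counts, the fold is at least the other level over 3 counts in that group, the 95% limit for 0 counts; from 1 to 3 counts the ratio carries a counting interval.

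Alternatives were RLE normalization, no filter on low counts, DESeq2, a fit of only the compared groups, leaving out each library in turn, a replicate block, the control instead of the editor line as reference, and camera with an estimated correlation. Added after the results were seen were fits without the hPGCLC ADAR libraries, without the hESC editor-only libraries and without the mitochondrially encoded genes, recounts of the overlaps, and 1 control library for each of 2 knockouts. Effects that share control libraries were set against 20 simulations without change. Editing events, processing body contents, proteins and cell proportions were not analysed here.

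Simulated data with 200 changed genes tested the fits. Recovery at 1.5-, 2- and 4-fold was 4.48, 34.3 and 77.3% (hPGCLC), 50.7, 67.2 and 97.0% (hESC), 2.99, 34.3 and 83.3% (controls) and 4.48, 43.3 and 66.7% (cell type differences). False calls numbered 9, 11, 9 and 4, and camera found only the shifted p53 target list. Correlated genes and unequal group spreads were left out.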

Results

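The series held gene counts for 36 RNA-seq libraries of the H1 human embryonic stem cell (hESC) line and its derivatives, in 18 groups of 2 libraries each. Human primordial germ cell-like cells (hPGCLC) were collected on day 4, and mesoderm, endoderm and ectoderm on day 5. Lines were a control, a DND1 knockout (DND1-KO), a NANOS3 knockout (NANOS3-KO), the double knockout (dKO, hPGCLC only), fusions of DND1 or NANOS3 to the RNA editor ADAR, a line with DND1-rAPOBEC1 and NANOS3-ADAR, and lines with ADAR or rAPOBEC1 alone. Assigned fragments per library ranged from 15183265 to 22100815 in 16 hESC libraries and from 3331530 to 15016237 in 14 hPGCLC libraries. Endoderm had 17860692 and 18410604, mesoderm 16334459 and 18041523 and ectoderm 14679695 and 15142512. The sample labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measured the spread between these libraries, which may be technical alone. Intervals and at-least folds covered counting error alone, and genes were ranked by fitted fold. Log2 fold changes have ± SE, levels are mean CPM and passing means adjusted p below 0.05. SEs pool a fit's spread and may be low for noisier pairs. Folds followed by 2 numbers are count ratios with 95% counting intervals, if a group held 3 counts or fewer. List counts adjusted over the list alone are given if they differ from those over all genes. The 2 hPGCLC libraries with ADAR alone carried hPGCLC day 4 in their titles but hESC as cell type, and were grouped by title. The alignment names of the 2 hESC control libraries start differently (D1 and H1), so that both are the same control rests on their titles (they correlate at r = 0.994).

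DND1 could not be measured in 34 of the 36 libraries: its count was 0 in every group, controls included, apart from 15698 and 18355 fragments in the hESC with DND1-rAPOBEC1 and NANOS3-ADAR. All exon bases of DND1 (chromosome 5, 140670794 to 140673576, minus strand, hg38) overlapped exons of WDR55 (140664868 to 140674124, plus strand), and the counting ignored strand, so a 0 here says nothing about DND1 expression or its loss. The file headers give the same counting for all 36 libraries, which does not account for the DND1 counts of those 2, and these were not set against other groups. WDR55, which takes in only the bases not shared, was lower in DND1-KO hPGCLC (-1.41 ± 0.18, adjusted p = 0.000444) and in dKO hPGCLC (-2.20 ± 0.19, adjusted p = 6.01e-06). NANOS3 (chromosome 19, 13862063 to 13880757) had 0 counts in all NANOS3-KO and dKO hPGCLC libraries. Control hPGCLC held 283 and 136 counts of it, DND1-KO 404 and 267, ADAR 253 and 158, DND1-ADAR 734 and 558 and NANOS3-ADAR 240 and 190. In hESC it was counted only in ADAR (0 and 1), NANOS3-ADAR (1421 and 1507) and the double fusion (5716 and 6070), so its loss could not be seen in NANOS3-KO hESC. Mesoderm held 0 and 0 counts, endoderm 2 and 0 and ectoderm 0 and 2. SOX4 (chromosome 6, 21593751 to 21598619), the gene in the series title, stood at 335 and 319 CPM of all assigned fragments in the 2 control hESC libraries, 313 and 300.0 in control hPGCLC, 233 and 199 in mesoderm, 225 and 229 in endoderm and 283 and 270.0 in ectoderm.

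**Figure D1:**
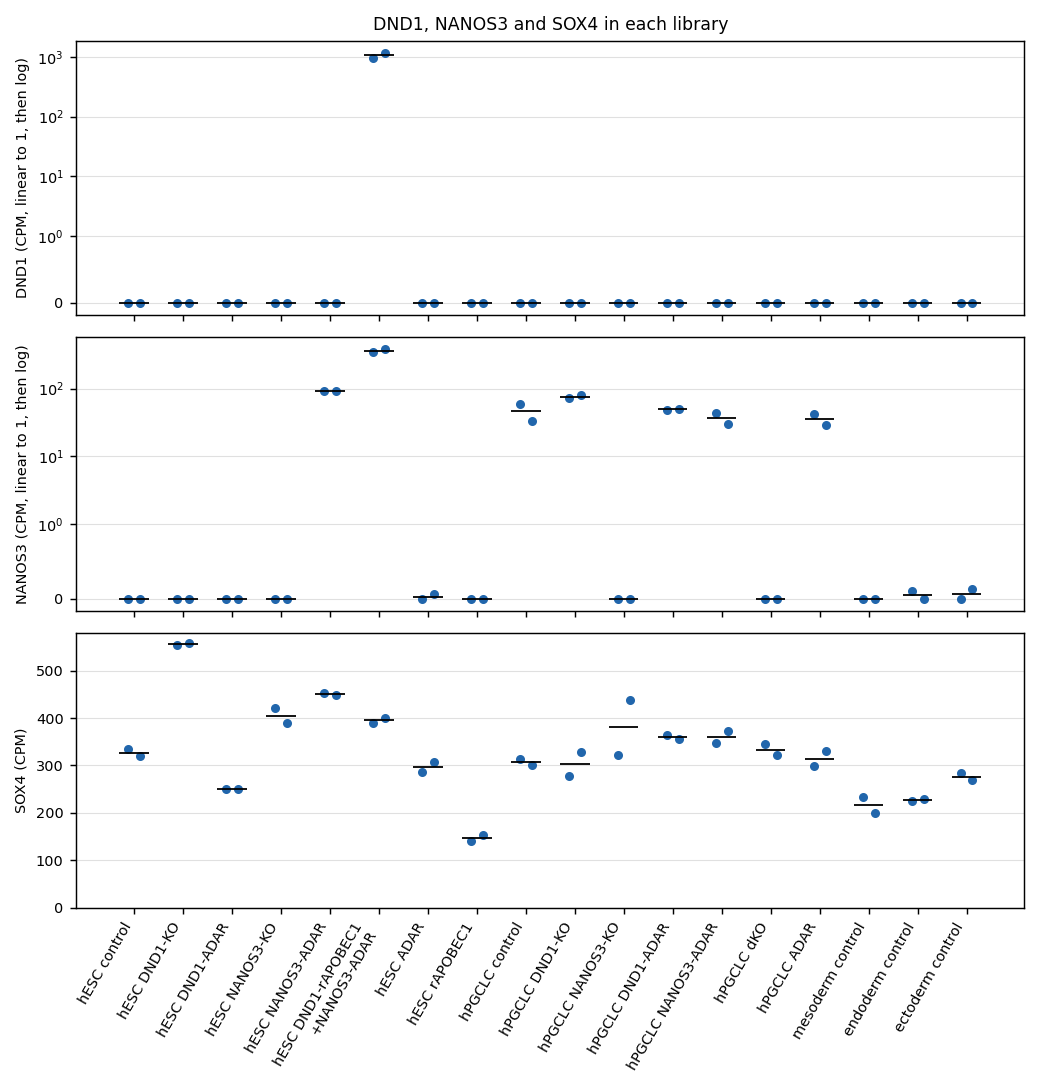
CPM of all assigned fragments for DND1, NANOS3 (both on a scale that is linear near 0 and logarithmic above) and SOX4 (linear) in each of the 36 libraries, one point per library. Black lines are means of the 2 libraries of a group, for example SOX4 at 554 and 558 CPM in DND1-KO hESC and 335 and 319 in control hESC.

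Genes next to DND1 were also lower in its knockout: ZMAT2 (-1.05 ± 0.11 in hESC, -0.83 ± 0.15 in hPGCLC) and HARS2 (-0.86 ± 0.14 in hESC). Neither overlaps DND1.

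**Figure D2:**
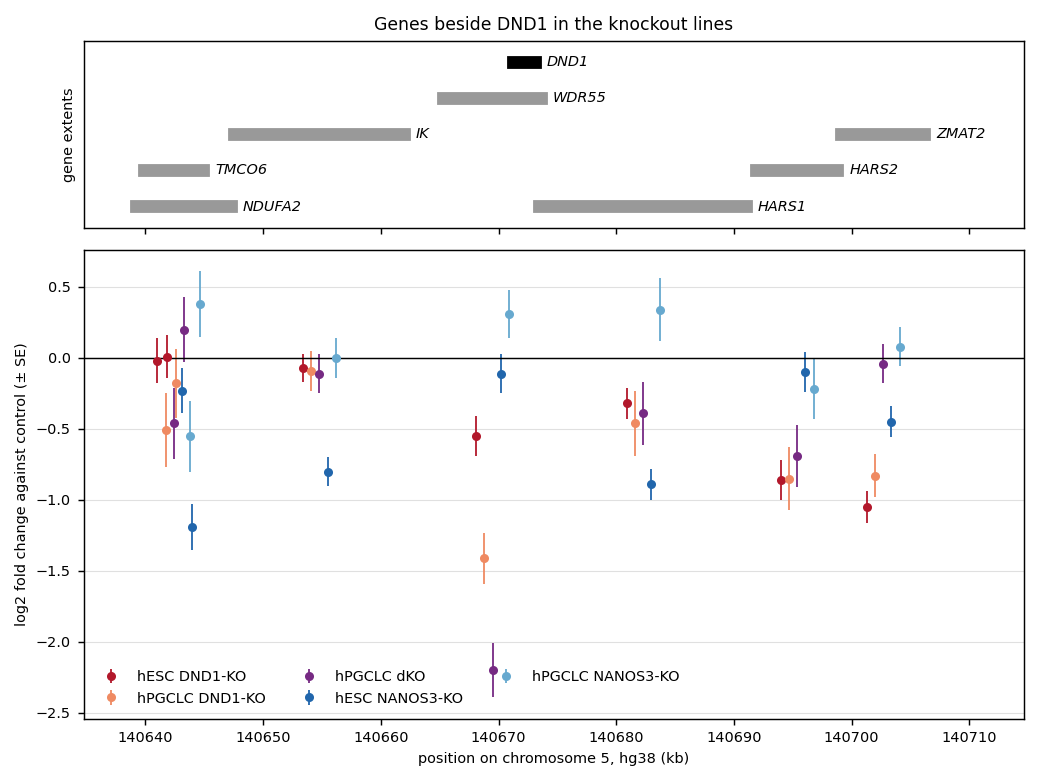
Positions of genes around DND1 on chromosome 5 (hg38, horizontal axis) and, for each gene, the log2 fold change ± SE in 5 knockout comparisons with 2 libraries per group. In DND1-KO hPGCLC WDR55 was at -1.41 ± 0.18 and IK, on its other side from HARS2 and ZMAT2, at -0.09 ± 0.14.

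Libraries with an editor alone stood apart among hESC. Mitochondrially encoded genes took 71.8 and 66.9% of fragments in the 2 rAPOBEC1 libraries and 32 and 23.7% in the 2 ADAR libraries, against 5.32 to 8.12% in the other hESC libraries. On the first principal component, 67.2% of variance, rAPOBEC1 lay at -190.0 and -165.0, ADAR at -74.9 and -47.3 and the other hESC between 30.0 and 47.2. These 4 libraries and the 2 of ADAR hPGCLC came from a later block of sample records, and no label gives a batch. In hPGCLC the 2 control libraries differed from each other: the mitochondrial share was 2.65 and 7.15%, the first component (30.0% of variance) placed them at 20.7 and -11.3, and their log2 CPM correlated across genes at r = 0.938, the lowest of the 18 groups. NANOS3-KO, dKO and NANOS3-ADAR hPGCLC lay between -41.3 and -28.8 on it and ADAR hPGCLC at 45.8 and 55.4. The spread between the 2 libraries, chi-squared per degree of freedom, ranged from 2.25 in DND1-ADAR hPGCLC to 65.1 in ectoderm.

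The control lines gave the reference for what each differentiation changed from hESC; the hPGCLC libraries were made with another kit, so that comparison carried both. Of 16 germ cell specification genes 15 rose and 1 fell, with SOX17 (16100-fold, 2890 to 638000), PRDM1 (8.53 ± 0.54), CXCR4 (8.22 ± 0.25) and LAMA4 (7.51 ± 0.26). The set was higher (adjusted p = 2.68e-11, and 0.0136 with estimated correlation). NANOS3, an RNA-binding germ cell factor, was at least 476-fold higher. 17 of 18 amnion and trophoblast genes rose and 0 fell (17 and 1 over the list alone), with HAND1 (2710-fold, 485 to 107000) and TFAP2A (1570-fold, 534 to 7600). Together they were higher (adjusted p = 5.05e-10, and 0.0393 with estimated correlation). Among the pluripotency genes (19 measured) 1 rose and 13 fell (1 and 14 over the list alone), with USP44 (-9.22 ± 0.44), SOX2 (-9.00 ± 0.54) and ZIC2 (-7.32 ± 0.34). Jointly they were lower (adjusted p = 2.83e-05, and 0.0328 with estimated correlation). From the HOX list, 16 of 31 members rose and 0 fell, with HOXB2 (at least 80.6-fold) and HOXA13 (at least 38.6-fold). As a group they were higher (adjusted p = 1.09e-06, and 0.0328 with estimated correlation). By fitted fold the largest increases were COL3A1 (at least 6150-fold), CRHBP (at least 3130-fold), SOX17, PDK4 (13300-fold, 2390 to 526000) and WNT2 (at least 780.0-fold), of which COL3A1 came mostly from library 1 (5259 and 160 counts in the 2 hPGCLC libraries). The largest decreases were HES3 (at least 121-fold), CXCL5 (at least 87.7-fold), RHBDL3 (at least 83.2-fold), PRKCB (at least 74.6-fold) and SOX3 (at least 71.5-fold). SOX4 stayed at -0.21 ± 0.17 (294 against 341 CPM, adjusted p = 0.340). Sets that passed only at the preset correlation were higher signalling response genes (19 rose and 0 fell of 20, adjusted p = 1.09e-09), endoderm genes (11 rose and 1 fell of 17, adjusted p = 0.00107) and mesoderm genes (12 rose and 2 fell of 19, adjusted p = 0.000944), the lowest at 0.0657 with estimated correlation. By edgeR 3788 rose and 3796 fell of 20344 tested. Their number, 7584, became 5041 and 4896 without hESC control library 1 and 2. At adjusted p = 0.0550, calls were lost by COL3A1 without the filter.

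In mesoderm, compared with hESC, the highest genes were HOXB9 (at least 5900-fold), CDX2 (at least 4900-fold), GRAP2 (at least 2920-fold), URAD (at least 2140-fold) and HOXB8 (at least 1900-fold). Lowest were ARFGEF3 (at least 634-fold), IDO1 (at least 583-fold), TRIML2 (at least 547-fold), FOXD3 (at least 413-fold) and ADRA2A (at least 400.0-fold). Of 31 HOX genes 30 rose and 0 fell. The whole list was higher (adjusted p = 9.96e-28, and 0.00260 with estimated correlation). 12 of 19 mesoderm genes rose and 2 fell, with HAND1 (6820-fold, 1220 to 269000), MSGN1 (at least 454-fold) and FOXC1 (at least 362-fold). The members together were higher (adjusted p = 0.000187, and 0.300 with estimated correlation). Among the pluripotency genes (19 measured) 0 rose and 18 fell, with NANOG (4540-fold, 815 to 179000), SOX2 (-11.21 ± 0.57) and GDF3 (at least 148-fold). Tested jointly they were lower (adjusted p = 2.76e-12, and 0.00557 with estimated correlation). SOX4 fell (-0.56 ± 0.17, 232 against 341 CPM, adjusted p = 0.0177). At the preset correlation alone the sets that passed were higher signalling response genes (15 rose and 4 fell of 20, adjusted p = 2.93e-05) and lower germ cell specification genes (4 rose and 10 fell of 16, adjusted p = 0.00316), the lowest at 0.117 with estimated correlation. By edgeR 3669 rose and 3954 fell of 20344 tested. Their number, 7623, became 11738 with only the compared groups, 4902 and 4905 without hESC control library 1 and 2 and 4929 and 4902 without mesoderm control library 1 and 2. The threshold was missed, at adjusted p between 0.0550 and 0.177, by SOX4 without hESC control library 1 or 2 or mesoderm control library 1 or 2.

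The same comparison in endoderm gave as highest PLCXD3 (at least 2250-fold), DIO3 (at least 1540-fold), SLC40A1 (at least 1500-fold), SOX17 (19900-fold, 3580 to 787000) and HNF4A (at least 721-fold), and as lowest MT1G (at least 186-fold), MT1H (at least 88.1-fold), MT1E (at least 62.5-fold), OLIG3 (at least 81.9-fold) and LRRTM3 (at least 79.2-fold). For endoderm genes, 16 of 17 rose and 0 fell, with SOX17, HNF4A and FOXA2 (6530-fold, 1170 to 258000). Camera placed the set higher (adjusted p = 1.62e-14, and 0.00925 with estimated correlation). Of 19 pluripotency genes 2 rose and 14 fell (2 and 15 over the list alone), with DPPA2 (-4.12 ± 0.60) and FGF2 (-4.02 ± 0.26). As a set they were lower (adjusted p = 1.32e-06, and 0.0255 with estimated correlation). SOX4 fell here too (-0.61 ± 0.17, 223 against 341 CPM, adjusted p = 0.0121). Only at the preset correlation did these sets pass, higher signalling response genes (17 rose and 2 fell of 20, adjusted p = 1.32e-06) and mesoderm genes (9 rose and 1 fell of 19, adjusted p = 0.00191) and lower p53 target genes (1 rose and 10 fell of 20, adjusted p = 0.00191), the lowest at 0.467 with estimated correlation. By edgeR 3568 rose and 3109 fell of 20344 tested. Their number, 6677, became 11334 with only the compared groups, 3909 and 3716 without hESC control library 1 and 2 and 3853 and 3993 without endoderm control library 1 and 2. Calls were lost, at adjusted p between 0.0673 and 0.123, by MT1G and MT1H with DESeq2 and SOX4 without endoderm control library 1 or 2 or hESC control library 1 or 2.

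For ectoderm against hESC, highest were NR2F1 (at least 6860-fold), MMRN1 (at least 2430-fold), NR2E1 (at least 1920-fold), FEZF2 (at least 1420-fold) and ST18 (at least 1300-fold). Lowest were TDGF1 (at least 8340-fold), VRTN (at least 2340-fold), POU5F1 (at least 2080-fold), C13orf42 (at least 1640-fold) and FOXH1 (at least 1020-fold). Among the ectoderm genes (19 measured) 17 rose and 0 fell, with NR2F1, NR2F2 (9670-fold, 1740 to 382000) and HES5 (at least 540.0-fold). The set was higher (adjusted p = 8.58e-09, and 0.0935 with estimated correlation). From the pluripotency list, 1 of 19 members rose and 15 fell (1 and 16 over the list alone). Together they were lower (adjusted p = 8.58e-09, and 0.0250 with estimated correlation). For processing body genes, 7 of 19 rose and 2 fell, with XRN1 (1.54 ± 0.21) and TNRC6C (1.25 ± 0.20). The set gave adjusted p = 0.606. SOX4 was not past the threshold (-0.36 ± 0.16, adjusted p = 0.0811). Passing at the preset correlation only were lower hypoxia and glycolysis genes (1 rose and 17 fell of 20, adjusted p = 6.89e-06) and G2 and M phase genes (0 rose and 13 fell of 20, adjusted p = 0.00127), the lowest at 0.458 with estimated correlation. By edgeR 5532 rose and 4975 fell of 20344 tested. SOX4 passed without ectoderm library 1 (-0.49, adjusted p = 0.0112).

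The DND1 knockout in hPGCLC, compared with control hPGCLC, asked what changed in day 4 cells of that line. Highest were TCEAL5 (48.1-fold, 8.23 to 1940), XKR7 (3.35 ± 0.75), ZNF528 (3.33 ± 0.33), EHHADH (2.51 ± 0.27) and PCDHB5 (2.28 ± 0.26). Next came IQCA1 (2.22 ± 0.39), PCDHGA10 (2.16 ± 0.26), PKIB (1.81 ± 0.27), JPH4 (1.77 ± 0.38) and VGLL3 (1.71 ± 0.32), with EHHADH a peroxisomal beta-oxidation enzyme and PCDHB5 and PCDHGA10 clustered protocadherins. The lowest 10 had 0 counts in both DND1-KO libraries: LYNX1 (at least 84.6-fold, from 28.5 CPM), ECHDC3 (at least 56.3-fold, from 18.9 CPM), PEG3 (at least 52.1-fold, from 17.6 CPM), VSTM5 (at least 33.5-fold, from 11.9 CPM) and DPEP3 (at least 31.9-fold, from 10.6 CPM). The other 5 were CCDC152 (at least 26.7-fold), TRIM61 (at least 25.4-fold), THEM6 (at least 25.4-fold), FPGT (at least 24.4-fold) and ZNF354C (at least 22.8-fold). SOX4 did not differ (0.01 ± 0.15, 306 ± 31.2 against 304 ± 8.04 CPM, adjusted p = 0.991). NANOS3 stood at 77.1 ± 4.27 against 45.5 ± 17.9 CPM (0.75 ± 0.27, adjusted p = 0.308). Among the signalling response genes (20 measured) 1 rose and 2 fell (1 and 6 over the list alone), with LEFTY2 (-4.82 ± 0.67), LEFTY1 (-4.51 ± 0.76) and ID1 (1.13 ± 0.17). Camera gave adjusted p = 0.0888. LEFTY1 and LEFTY2 encode NODAL inhibitors. From the mesoderm list, 0 of 15 members rose and 1 fell (0 and 5 over the list alone), with TBXT (-0.75 ± 0.16). The whole list was lower (adjusted p = 0.000950, and 0.532 with estimated correlation). 1 of 20 G2 and M phase genes rose and 0 fell, with TPX2 (1.32 ± 0.14). The members together were higher (adjusted p = 0.00529, and 0.545 with estimated correlation). Named after their values were seen, the pluripotency marker ZFP42 (-1.29 ± 0.16) fell and the processing body component TNRC6C (0.77 ± 0.15) rose; these 2 and TPX2 missed the threshold with only the compared groups, TNRC6C also without DND1-KO library 1 or control library 2. Counts of genes that rose and fell were 0 and 0 of 17 germ cell specification, 0 and 1 of 18 pluripotency, 1 and 0 of 19 processing body and 0 and 0 of 18 CCR4-NOT deadenylation genes. Sets that passed only at the preset correlation were higher cytosolic ribosomal protein genes (0 rose and 0 fell of 30, adjusted p = 0.00529) and interferon response genes (0 rose and 0 fell of 12, adjusted p = 0.0108) and lower HOX genes (0 rose and 0 fell of 19, adjusted p = 0.000950), the lowest at 0.0803 with estimated correlation. By edgeR 45 rose and 81 fell of 15761 tested. Their number, 126, became 28 with only the compared groups, 259 with DESeq2 and 484 without the filter. It was 1443 without control library 1 and 55 without DND1-KO library 1. Calls were lost, at adjusted p between 0.0533 and 0.532, by 14 of 27 genes with only the compared groups, XKR7 with a replicate block, 9 of 27 genes without DND1-KO library 1, LEFTY1, VGLL3 and XKR7 without DND1-KO library 2, 6 of 27 genes without control library 2 and JPH4 and XKR7 without the hPGCLC ADAR libraries. NANOS3 passed without the filter (0.73, adjusted p = 0.0288) and without control library 1 (1.23, adjusted p = 0.0113).

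The NANOS3 knockout in hPGCLC asked the same of its line. NANOS3 itself (at least 193-fold) and CHCHD2 (928-fold, 166 to 36700), which encodes a mitochondrial protein, were the lowest. They were followed by TRIM61 (at least 35.9-fold), ZNF558 (-3.97 ± 0.30), FGF19 (-3.67 ± 0.80), PALM3 (-3.52 ± 0.51), PEG3 (-3.20 ± 0.54), NLRP7 (-2.88 ± 0.44), NGFR (-2.81 ± 0.63) and CLEC2L (-2.52 ± 0.55). Highest were SLITRK6 (115-fold, 20.4 to 4570), CTSF (4.43 ± 0.65), OLFM3 (4.14 ± 0.77), S100A6 (4.13 ± 0.44) and SPP1 (3.84 ± 0.63). Next came MT1G (3.82 ± 0.71), MMP9 (3.78 ± 0.80), IL1RAP (2.99 ± 0.59), CLSTN2 (2.78 ± 0.45) and NIBAN1 (2.28 ± 0.49). SOX4 was 394 ± 87.5 against 304 ± 8.04 CPM, that is 0.37 ± 0.15 (adjusted p = 0.162). No list moved as a set, the lowest adjusted p being 0.22. Few members passed, and they are named after their values were seen: the germ cell gene ALPL (-0.73 ± 0.13) fell, the pluripotency genes LIN28B (0.85 ± 0.15) and FGF2 (0.78 ± 0.17) rose with the mesoderm gene TBXT (0.72 ± 0.15) and the ligand WNT3 (1.02 ± 0.24), and SOX13 (-0.76 ± 0.19) and PAN2 (-0.97 ± 0.22) fell. Genes that rose and fell numbered 0 and 1 of 17 germ cell specification, 2 and 0 of 18 pluripotency, 0 and 0 of 19 processing body, 0 and 1 of 18 CCR4-NOT deadenylation and 0 and 1 of 15 SOX transcription factor genes. By edgeR 205 rose and 262 fell of 15761 tested. Their number, 467, became 2 with only the compared groups, 295 without the hPGCLC ADAR libraries and 865 with DESeq2. It was 1167 without the filter, 1732 without control library 2 and 91 without NANOS3-KO library 2. No longer past the threshold, at adjusted p between 0.05 and 0.490, were 25 of 27 genes with only the compared groups, SLITRK6 with a replicate block or without control library 2, 8 of 27 genes without NANOS3-KO library 1, 12 of 27 genes without NANOS3-KO library 2, 10 of 27 genes without control library 1 and 4 of 27 genes without the hPGCLC ADAR libraries.

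The line with both genes targeted, dKO hPGCLC, was compared with control in the same way. Lowest were CHCHD2 (at least 343-fold), NANOS3 (at least 214-fold), ZNF558 (at least 116-fold), ACTN3 (at least 33.2-fold) and PEG3 (245-fold, 43.4 to 9740). Next came LEFTY1 (-5.60 ± 0.79), NLRP7 (-5.53 ± 0.56), TRIM61 (39.8-fold, 13.1 to 197), NGFR (-5.01 ± 0.79) and LEFTY2 (-4.98 ± 0.66). Highest were CTSF (5.49 ± 0.62), TCEAL5 (49.0-fold, 8.52 to 1960), MT1G (4.82 ± 0.68), LGALS16 (16.5-fold, 5.45 to 82.0) and INHBB (3.33 ± 0.84). Next came OLFM3 (3.29 ± 0.79), TACR1 (3.28 ± 0.55), BSND (3.27 ± 0.76), ENTPD3 (3.10 ± 0.67) and MUC15 (3.01 ± 0.68). SOX4 did not pass here either (0.15 ± 0.15, 339 ± 21.4 against 304 ± 8.04 CPM, adjusted p = 0.593). 4 of 17 germ cell specification genes rose and 0 fell (4 and 1 over the list alone), with PRDM14 (1.36 ± 0.16), TFCP2L1 (1.14 ± 0.15), PRDM1 (1.00 ± 0.14) and ARID5B (0.66 ± 0.16). The set gave adjusted p = 0.0638. For pluripotency genes, 3 of 18 rose and 1 fell (4 and 5 over the list alone), with LIN28B (0.96 ± 0.15), FGF2 (0.93 ± 0.17), DPPA4 (-0.76 ± 0.14) and NANOG (0.73 ± 0.16). Camera gave adjusted p = 0.895. Of 20 signalling response genes 0 rose and 3 fell (0 and 7 over the list alone), with LEFTY1, LEFTY2 and NODAL (-3.04 ± 0.55). As a set they were lower (adjusted p = 0.0112, and 0.864 with estimated correlation). Named after their values were seen, the decapping enzyme DCP2 (0.58 ± 0.14) and TNRC6B (0.79 ± 0.20) of the processing body list rose, BTG2 (-0.92 ± 0.15) of the deadenylation list fell and TBXT (1.19 ± 0.15) rose. Numbers that rose and fell were 2 and 0 of 19 processing body, 0 and 1 of 18 CCR4-NOT deadenylation and 1 and 1 of 15 mesoderm genes. By edgeR 423 rose and 415 fell of 15761 tested. Their number, 838, became 34 with only the compared groups, 1428 without the filter, 1737 without control library 2 and 126 and 128 without dKO library 1 and 2. At adjusted p between 0.0503 and 0.321, calls were lost by LGALS16 with RLE normalization or with a replicate block, 24 of 32 genes with only the compared groups, 6 of 33 genes without control library 1, 4 of 33 genes without control library 2, 15 of 33 genes without dKO library 1 and 18 of 33 genes without dKO library 2.

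**Figure D3:**
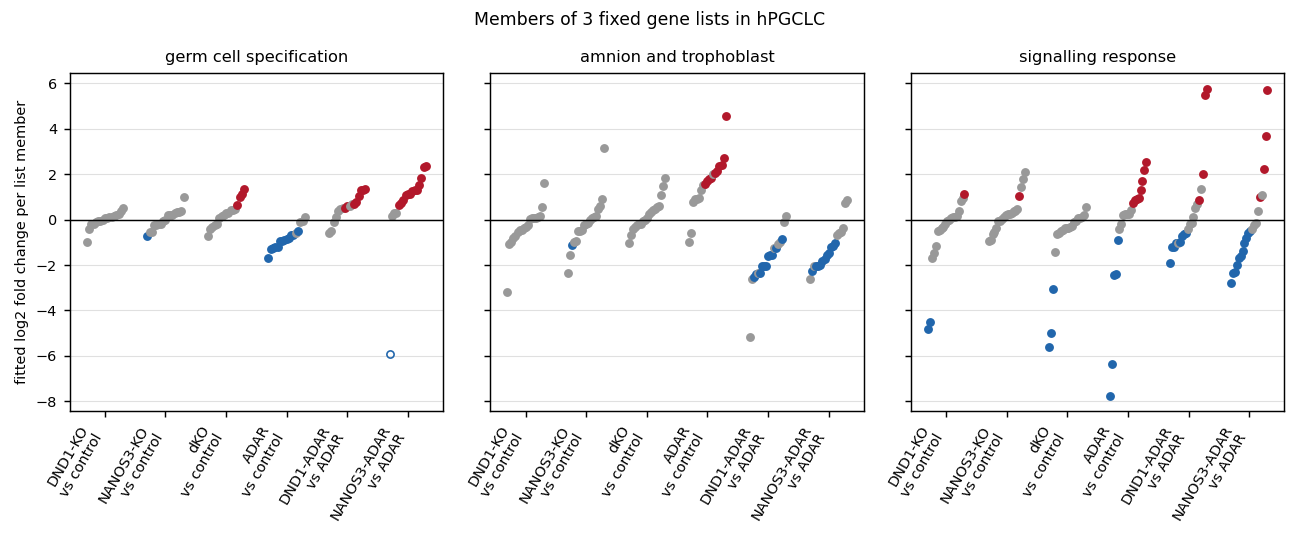
Log2 fold change (vertical axis) of measured members of selected lists in hPGCLC, one point per gene: knockouts and ADAR against control, fusions against ADAR. Red (higher) and blue (lower) points passed, grey did not, and open points had a group with 3 counts or fewer.

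PEG3 and TRIM61 were lowered in both single knockouts and in dKO, while NANOS3, CHCHD2, ZNF558, NLRP7 and NGFR fell, and CTSF, MT1G and OLFM3 rose, in NANOS3-KO and dKO alike. For NANOS3-KO with dKO, 78 genes rose and 73 fell in both, against 5.50 and 6.90 expected for independent comparisons, and 1 moved in opposite directions. For DND1-KO with dKO, 12 genes rose and 14 fell in both, against 1.21 and 2.13 expected likewise, and 7 moved in opposite directions. For DND1-KO with NANOS3-KO, 5 genes rose and 4 fell in both, against 0.585 and 1.35 expected likewise, and 12 moved in opposite directions. Effects correlated across 15761 genes, which are not independent replicates, at r = 0.516 for NANOS3-KO with dKO, 0.286 for DND1-KO with dKO and 0.135 for the 2 single knockouts. The 3 comparisons used the same 2 control libraries, which alone gave mean r = 0.561, 0.527 and 0.522 in 20 simulations without any change. Given 1 control library each, a test added after the results were seen, the 2 assignments gave r = -0.057 and 0.075 for NANOS3-KO with dKO, 0.005 and -0.191 for DND1-KO with dKO and -0.063 and -0.351 for the single knockouts, so the correlations above depended on the shared controls. Then 142 and 102 genes moved the same way in NANOS3-KO and dKO and 117 and 55 in opposite directions.

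Whether the dKO effect equalled the sum of the single effects was tested as a difference of differences, with CPM in control, DND1-KO, NANOS3-KO and dKO given in this order. Above the sum lay, among others, genes with 0 counts in DND1-KO, where any level in dKO exceeds the sum: LYNX1 (28.5, 0, 16.1 and 16.6), ECHDC3 (18.9, 0, 19 and 13.6), DPEP3 (10.6, 0, 3.20 and 3.69) and THEM6 (8.53, 0, 5.33 and 7.04), up to adjusted p = 0.00686. Below it lay ZNF558 (25.3, 15.6, 1.58 and 0), IQCA1 (3.15, 14.6, 4.55 and 2.55), THRB (6.95, 13.2, 19.1 and 5.61), ZNF528 (3.77, 37.5, 10.5 and 16.3) and PKIB (9.52, 33.6, 11.2 and 6.68), up to adjusted p = 0.0184. SOX4 gave -0.23 ± 0.21 (adjusted p = 0.737). From the G2 and M phase list, 0 of 20 members lay above and 1 below, with TPX2 (-1.59 ± 0.19). The set was lower (adjusted p = 0.000205, and 0.467 with estimated correlation). At the preset correlation only, sets that passed were higher germ cell specification genes (0 above and 0 below of 17, adjusted p = 0.0219) and HOX genes (0 above and 0 below of 19, adjusted p = 0.0124) and lower G1 and S phase genes (0 above and 0 below of 20, adjusted p = 0.0112), the lowest at 0.252 with estimated correlation. By edgeR 62 lay above the sum and 36 below it of 15761 tested. Their number, 98, became 26 with only the compared groups, 246 with DESeq2 and 467 without the filter. It was 848 and 185 without control library 1 and 2, 47 without DND1-KO library 1, 194 and 64 without NANOS3-KO library 1 and 2 and 58 and 30 without dKO library 1 and 2. The threshold was missed, at adjusted p between 0.0595 and 0.233, by 4 of 10 genes with only the compared groups, IQCA1, THEM6 and ZNF558 without DND1-KO library 1, ZNF558 without dKO library 1 and IQCA1, ZNF528 and ZNF558 without dKO library 2.

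The hPGCLC with ADAR alone were compared with control hPGCLC to see what the editor line carried. For amnion and trophoblast genes, 10 of 19 rose and 0 fell (14 and 0 over the list alone), with WNT6 (4.56 ± 0.69), VTCN1 (2.72 ± 0.39) and HAND1 (2.39 ± 0.21). Together they were higher (adjusted p = 2.12e-09, and 0.0562 with estimated correlation). Of 17 germ cell specification genes 0 rose and 13 fell, with UTF1 (-1.68 ± 0.22), ARID5B (-1.30 ± 0.17), CD38 (-1.23 ± 0.28) and TFCP2L1 (-1.20 ± 0.15). Jointly they were lower (adjusted p = 4.57e-09, and 0.0543 with estimated correlation). 6 of 19 HOX genes rose and 0 fell (9 and 1 over the list alone), with HOXB1 (at least 20.9-fold), HOXD13 (at least 4.80-fold) and HOXB5 (3.82 ± 0.81). As a group they were higher (adjusted p = 2.07e-05, and 0.0312 with estimated correlation). Among the G1 and S phase genes (20 measured) 0 rose and 2 fell (0 and 6 over the list alone), with CDT1 (-0.61 ± 0.18) and RRM2 (-0.58 ± 0.16). The whole list was lower (adjusted p = 0.00473, and 0.676 with estimated correlation). The largest increases were HOXB1, PON3 (at least 19.9-fold), TRPM3 (at least 15.4-fold), UPK2 (81.8-fold, 14.4 to 3260) and MYCT1 (81.0-fold, 14.2 to 3230). The largest decreases were PEG3 (at least 70.4-fold), LEFTY2 (-7.75 ± 0.82), LYNX1 (114-fold, 38.7 to 559), TRIM61 (103-fold, 18.0 to 4120) and LEFTY1 (-6.35 ± 0.88). The ADAR gene (-0.18 ± 0.12, adjusted p = 0.379) and SOX4 (0.00 ± 0.15, adjusted p = 0.996) did not pass. By edgeR 733 rose and 729 fell of 15761 tested. Their number, 1462, became 316 with only the compared groups, 2214 without control library 1 and 816 and 434 without ADAR library 1 and 2. At adjusted p between 0.0504 and 0.292, calls were lost by 5 of 20 genes with only the compared groups, TRPM3 with a replicate block, 4 of 21 genes without ADAR library 1 or control library 2, 6 of 21 genes without ADAR library 2 and CDT1, HOXD13 and TRPM3 without control library 1.

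DND1-ADAR hPGCLC were compared with ADAR hPGCLC. The ADAR libraries are the reference here and the tested group above, so effects opposite to those of the ADAR line are expected without any effect of a fusion. For germ cell specification genes, 8 of 17 rose and 0 fell (13 and 1 over the list alone), with PRDM1 (1.33 ± 0.14), TFCP2L1 (1.31 ± 0.15) and KIT (1.31 ± 0.32). The members together were higher (adjusted p = 1.65e-05, and 0.188 with estimated correlation). Of 19 amnion and trophoblast genes 0 rose and 11 fell (0 and 13 over the list alone), with VTCN1 (-2.54 ± 0.36), WNT6 (-2.38 ± 0.52) and GABRP (-2.34 ± 0.35). Tested jointly they were lower (adjusted p = 1.09e-08, and 0.188 with estimated correlation). The largest increases were ZNF717 (at least 28.8-fold), ZNF736 (at least 20.0-fold), LEFTY2 (5.77 ± 0.80), TRIM4 (56.1-fold, 19.1 to 273) and LEFTY1 (5.50 ± 0.90). The largest decreases were ERVV-2 (203-fold, 35.5 to 8100), CYP19A1 (-5.93 ± 1.30), CHCHD2 (-5.86 ± 0.34), S100A6 (-4.32 ± 0.42) and PON3 (-4.24 ± 0.84). SOX4 stayed (0.20 ± 0.15, adjusted p = 0.442), NANOS3 stood at 47.8 against 34.3 CPM (0.48 ± 0.26, adjusted p = 0.291) and ADAR rose (0.41 ± 0.12, adjusted p = 0.0365). The preset correlation alone also gave higher pluripotency genes (5 rose and 1 fell of 18, adjusted p = 0.00466) and lower replication-dependent histone genes (0 rose and 2 fell of 5, adjusted p = 0.00996), the lowest at 0.258 with estimated correlation. By edgeR 811 rose and 965 fell of 15761 tested. Their number, 1776, became 818 with the control as reference, 4616 with only the compared groups, 435 and 499 without DND1-ADAR library 1 and 2 and 967 and 494 without ADAR library 1 and 2. Calls were lost, at adjusted p between 0.0526 and 0.767, by CYP19A1 without the filter, 8 of 17 genes with the control as reference, ADAR and KIT without ADAR library 1 and 5 of 17 genes without ADAR library 2 or DND1-ADAR library 1 or 2. With the control as reference 288 of all 1776 calls were kept and 24 turned past the threshold. Of the 17 named genes 6 turned, all not past it (adjusted p 0.0906 to 0.847). NANOS3 passed with only the compared groups (0.46, adjusted p = 0.0319).

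NANOS3-ADAR hPGCLC had the same reference, to which the same applies. Among the germ cell specification genes (17 measured) 13 rose and 1 fell, with DPPA3 (lower, at least 4.11-fold), TFCP2L1 (2.38 ± 0.16), PRDM14 (2.30 ± 0.17) and PRDM1 (1.84 ± 0.14). Camera placed the set higher (adjusted p = 9.07e-08, and 0.0738 with estimated correlation). From the amnion and trophoblast list, 0 of 19 members rose and 11 fell, with HEY1 (-2.28 ± 0.28) and WNT6 (-2.04 ± 0.54). As a set they were lower (adjusted p = 0.000267, and 0.342 with estimated correlation). For HOX genes, 1 of 19 rose and 8 fell (1 and 9 over the list alone). The set was lower (adjusted p = 0.00139, and 0.0738 with estimated correlation). Of 15 mesoderm genes 2 rose and 8 fell (2 and 10 over the list alone), with FOXF1 (-4.10 ± 0.94) and HAND2 (-3.73 ± 0.68). Together they were lower (adjusted p = 0.0182, and 0.618 with estimated correlation). The largest increases were OLFM3 (250.0-fold, 44.4 to 9900), TRIM61 (176-fold, 31.1 to 6990), TRIM4 (58.6-fold, 19.7 to 287), LEFTY2 (5.71 ± 0.80) and PYDC1 (56.4-fold, 15.2 to 471). The largest decreases were FGA (at least 31.0-fold), HOXB1 (at least 26.3-fold), CHST9 (at least 22.8-fold), MMP1 (at least 20.3-fold) and HABP2 (at least 19.3-fold). SOX4 (0.30 ± 0.15, adjusted p = 0.143) and NANOS3 (0.17 ± 0.27, adjusted p = 0.684) did not pass, and ADAR rose (0.37 ± 0.12, adjusted p = 0.0339). The preset correlation alone also gave lower hypoxia and glycolysis genes (1 rose and 12 fell of 19, adjusted p = 0.00308) and fibroblast genes (0 rose and 4 fell of 16, adjusted p = 0.0122), the lowest at 0.618 with estimated correlation. By edgeR 2005 rose and 1974 fell of 15761 tested. Their number, 3979, became 1874 with the control as reference, 2050 without NANOS3-ADAR library 1 and 2535 and 1726 without ADAR library 1 and 2. No longer past the threshold, at adjusted p between 0.0513 and 1.00, were ADAR without the filter, 9 of 19 genes with the control as reference, ADAR and DPPA3 without ADAR library 1, 4 of 19 genes without ADAR library 2 or NANOS3-ADAR library 1 and ADAR, DPPA3 and WNT6 without NANOS3-ADAR library 2. With the control as reference 1197 of all 3979 calls were kept and 31 turned past the threshold. Of the 19 named genes 3 turned, 2 of them not past it (adjusted p 0.0551 to 0.739).

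Fusion and knockout effects, which had no library in common, differed by gene. OLFM3 rose in NANOS3-KO against control and in NANOS3-ADAR against ADAR, while TRIM61 fell in the first and rose in the second. For NANOS3, 101 genes rose and 126 fell in both, against 26.1 and 32.8 expected by chance, and 20 moved oppositely (r = 0.322). For DND1, 2 rose and 5 fell in both, against 2.32 and 4.96, and 72 moved oppositely (r = -0.107). PEG3, LYNX1 and TRIM61, low in DND1-KO, were also low in ADAR hPGCLC, the reference of the fusion comparison.

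DND1-KO hESC showed endoderm and mesoderm genes. 14 of 17 endoderm genes rose and 0 fell (15 and 0 over the list alone), with TTR (at least 11.1-fold), FOXA2 (144-fold, 25.5 to 5720) and SOX17 (73.8-fold, 12.9 to 2950). Jointly they were higher (adjusted p = 4.08e-07, and 0.0450 with estimated correlation). From the mesoderm list, 8 of 13 members rose and 0 fell, with FOXC1 (at least 22.5-fold), TBXT (31.0-fold, 8.27 to 261), EOMES (3.65 ± 0.45) and MIXL1 (3.14 ± 0.36). As a group they were higher (adjusted p = 0.000635, and 0.0450 with estimated correlation). For pluripotency genes, 4 of 19 rose and 11 fell (4 and 13 over the list alone), with FGF2 (-1.70 ± 0.10), ZFP42 (-1.18 ± 0.09) and PODXL (-1.13 ± 0.11). The whole list was lower (adjusted p = 0.00136, and 0.150 with estimated correlation). Of its core factors, named after their values were seen, SOX2 fell (-0.89 ± 0.10), NANOG rose (0.55 ± 0.10) and POU5F1 did not pass (0.33 ± 0.63, adjusted p = 0.740). SOX4 rose to 482 ± 6.01 against 295 ± 7.88 CPM (0.71 ± 0.09, adjusted p = 3.81e-07). Of 20 G1 and S phase genes 2 rose and 12 fell, with UHRF1 (-0.93 ± 0.11), CCND2 (0.83 ± 0.12), RRM2 (-0.59 ± 0.10) and PCNA (-0.57 ± 0.10). The members together were lower (adjusted p = 0.00136, and 0.0488 with estimated correlation). Among the G2 and M phase genes (20 measured) 9 rose and 0 fell, with TPX2 (1.44 ± 0.09) and KIF20A (0.54 ± 0.11). Tested jointly they were higher (adjusted p = 0.0315, and 0.289 with estimated correlation). 2 of 19 processing body genes rose and 3 fell, with TNRC6C (1.42 ± 0.12), MOV10 (-1.15 ± 0.15) and TNRC6A (-0.49 ± 0.11). Camera gave adjusted p = 0.948. From the later germ cell list, 0 of 10 members rose and 3 fell, with MOV10L1 (14.5-fold, 2.17 to 614), PIWIL2 (-2.61 ± 0.23) and DAZL (-1.73 ± 0.31). The set gave adjusted p = 0.285. The largest increases were ZNF492 (at least 89.0-fold), CST1 (6.55 ± 0.65), DNAJC15 (6.53 ± 0.46), APLNR (5.27 ± 0.79) and ZNF528 (5.16 ± 0.32). The largest decreases were PEG3 (at least 384-fold), LYNX1 (at least 114-fold), ZNF726 (at least 84.1-fold), FPGT (at least 74.9-fold) and TRIM4 (-7.46 ± 0.34). Elsewhere the higher and lower members were 3 and 2 of 18 CCR4-NOT deadenylation, 7 and 4 of 17 SOX transcription factor, 8 and 4 of 20 signalling response, 8 and 4 of 18 germ cell specification, 2 and 0 of 8 replication-dependent histone and 3 and 7 of 20 p53 target genes. By edgeR 3265 rose and 3147 fell of 19907 tested. The threshold was missed, at adjusted p between 0.0630 and 0.176, by MOV10L1 with DESeq2 or without DND1-KO library 2, TTR without DND1-KO library 1 and MOV10L1 and TNRC6A without control library 1.

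NANOS3-KO hESC had lower G1 and S phase genes, although NANOS3 itself was not counted in hESC. 0 of 20 G1 and S phase genes rose and 17 fell, with UHRF1 (-1.25 ± 0.11), MCM5 (-1.19 ± 0.09), PCNA (-1.03 ± 0.10) and RRM2 (-0.99 ± 0.10). The set was lower (adjusted p = 1.34e-07, and 0.00993 with estimated correlation). From the cytosolic ribosomal protein list, 1 of 30 members rose and 17 fell (1 and 18 over the list alone), with RPL8 (-1.59 ± 0.09) and RPL27 (-1.12 ± 0.09). Together they were lower (adjusted p = 2.13e-05, and 0.828 with estimated correlation). For hypoxia and glycolysis genes, 0 of 20 rose and 10 fell (1 and 12 over the list alone), with ADM (-2.31 ± 0.25) and SLC2A1 (-1.26 ± 0.10). Jointly they were lower (adjusted p = 0.00984, and 0.828 with estimated correlation). Of 19 processing body genes 3 rose and 6 fell, with XRN1 (0.74 ± 0.14), MOV10 (-0.70 ± 0.15), DCP2 (0.60 ± 0.10) and EDC4 (-0.58 ± 0.11). The set gave adjusted p = 0.731. 4 of 10 later germ cell genes rose and 0 fell, with MAEL (2.90 ± 1.04), TDRD6 (2.01 ± 0.61) and MOV10L1 (1.83 ± 0.72). Camera gave adjusted p = 0.138. SOX4 did not pass (327 ± 20.9 against 295 ± 7.88 CPM, 0.15 ± 0.09, adjusted p = 0.190). The largest increases were NPTX1 (4.56 ± 0.26), OR52A1 (4.29 ± 0.48), ABHD12B (4.06 ± 0.20), HHLA1 (3.76 ± 0.29) and CSMD1 (3.72 ± 0.25). The largest decreases were CHCHD2 (at least 1060-fold), TRIM61 (-4.70 ± 0.59), MRPL12 (-3.95 ± 0.23), VGF (-3.79 ± 0.18) and AMH (-3.79 ± 0.25). Genes that rose and fell were 1 and 4 of 18 CCR4-NOT deadenylation, 8 and 3 of 18 germ cell specification and 2 and 5 of 17 SOX transcription factor genes. By edgeR 3640 rose and 4129 fell of 19907 tested. Calls were lost, at adjusted p between 0.0526 and 0.199, by MAEL and MOV10L1 with DESeq2 or without the filter or without NANOS3-KO library 1, MOV10L1 with a replicate block, MOV10L1 and TDRD6 without NANOS3-KO library 2 and MAEL, MOV10L1 and TDRD6 without control library 1 or 2.

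**Figure D4:**
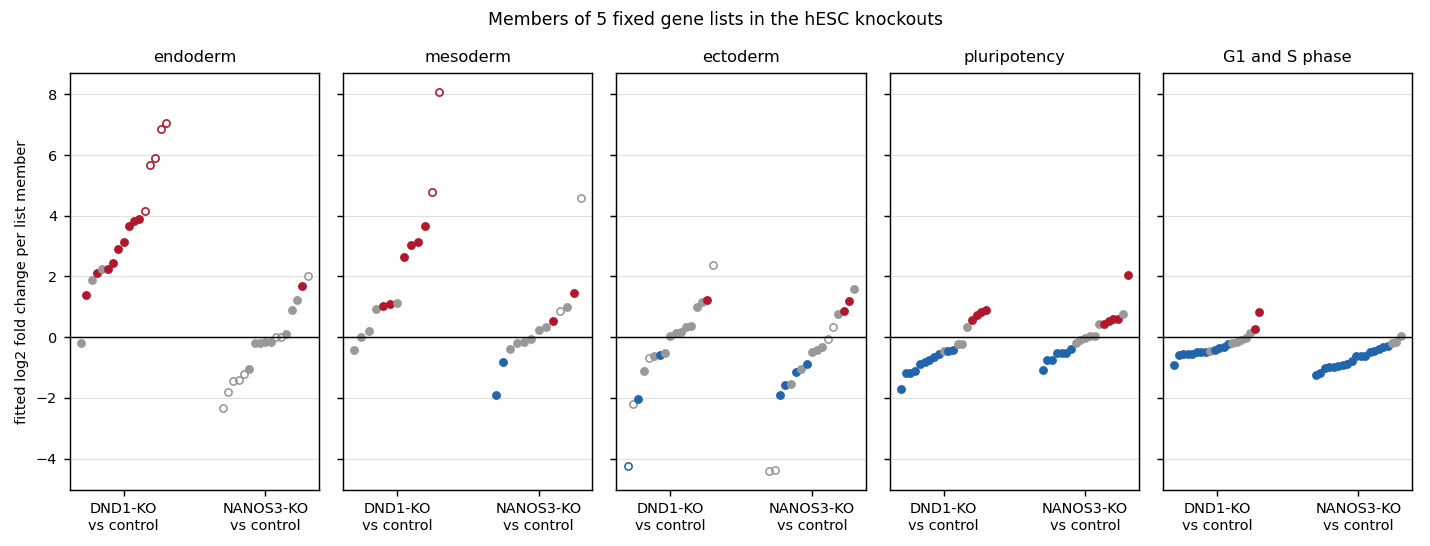
Log2 fold change against control hESC (vertical axis) of each measured member of selected gene lists in DND1-KO and NANOS3-KO hESC, one point per gene. Red (higher) and blue (lower) points passed, grey did not, and open points had a group with 3 counts or fewer.

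The hESC with an editor alone were compared with control hESC; they held 32 and 23.7% (ADAR) and 71.8 and 66.9% (rAPOBEC1) mitochondrial fragments against 5.86 and 6.14% in control. In the ADAR line the highest genes were ANKRD1 (at least 2110-fold), CST1 (10.23 ± 0.60), FOXA2 (1260-fold, 226 to 50000), SOX17 (951-fold, 170.0 to 37600) and EVX1 (at least 62.5-fold). Lowest were OLIG3 (at least 58.9-fold), ADRA2A (993-fold, 178 to 39300), TTYH1 (-5.92 ± 0.29), VIPR2 (-5.72 ± 0.86) and PEG3 (-5.57 ± 0.24). The ADAR gene was lower (-2.25 ± 0.09, 109 against 516 CPM), not higher. SOX4 gave 0.16 ± 0.09 (adjusted p = 0.132). 13 of 13 mitochondrially encoded genes rose and 0 fell. The members together were higher (adjusted p = 2.05e-07, and 0.231 with estimated correlation). For cytosolic ribosomal protein genes, 26 of 30 rose and 3 fell. Tested jointly they were higher (adjusted p = 6.23e-08, and 0.231 with estimated correlation). The preset correlation alone also gave lower hypoxia and glycolysis genes (0 rose and 16 fell of 20, adjusted p = 4.26e-06), G1 and S phase genes (1 rose and 14 fell of 20, adjusted p = 0.000260), processing body genes (2 rose and 12 fell of 19, adjusted p = 0.0172) and CCR4-NOT deadenylation genes (3 rose and 11 fell of 18, adjusted p = 0.0209), the lowest at 0.0945 with estimated correlation. By edgeR 5867 rose and 5855 fell of 19907 tested.

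In the rAPOBEC1 line, of 13 mitochondrially encoded genes 13 rose and 0 fell. Camera placed the set higher (adjusted p = 2.21e-10, and 0.352 with estimated correlation). The preset correlation alone gave higher endoderm genes (10 rose and 1 fell of 17, adjusted p = 0.00969) and lower hypoxia and glycolysis genes (0 rose and 16 fell of 20, adjusted p = 2.75e-05), the lowest at 0.352 with estimated correlation. Highest were ANKRD1 (at least 286-fold), SPATA16 (at least 104-fold), CEACAM5 (at least 92.1-fold), FOXA2 (1080-fold, 194 to 42900) and REG4 (at least 62.5-fold). Among the lowest were OLIG3 (at least 27.8-fold), ALPG (52.7-fold, 14.4 to 437), ADRA2A (-5.41 ± 0.67) and PEG3 (-4.96 ± 0.27), and ADAR was lower (-1.90 ± 0.09). SOX4 rose (0.43 ± 0.09, adjusted p = 0.000146), and also without the mitochondrially encoded genes (0.48, past the threshold), but per assigned fragment it was lower than in control (140.0 and 154 against 335 and 319 CPM), so its direction depends on the scaling. By edgeR 5700 rose and 6403 fell of 19907 tested.

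DND1-ADAR hESC were compared with ADAR hESC, whose mitochondrial share differed (7.85 and 7.40% against 32 and 23.7%). Highest were ADRA2A (214-fold, 38.2 to 8490), NPTX1 (6.79 ± 0.46), HLA-DOA (5.32 ± 0.37), KAT6B (5.08 ± 0.36) and PCDHAC2 (5.06 ± 0.48). Lowest were ANKRD1 (-9.21 ± 0.44), CST1 (-7.89 ± 0.48), LRRC61 (287-fold, 50.9 to 11400), CST4 (279-fold, 49.5 to 11100) and NPPB (-7.58 ± 0.40). SOX4 fell (217 ± 1.99 against 328 ± 18.0 CPM, -0.60 ± 0.09, adjusted p = 1.42e-06) and ADAR rose (2.02 ± 0.09) but not against control (-0.22). Among the processing body genes (19 measured) 10 rose and 2 fell, with TNRC6A (2.43 ± 0.13). As a set they were higher (adjusted p = 0.0162, and 0.132 with estimated correlation). From the mitochondrially encoded list, 0 of 13 members rose and 13 fell. The set was lower (adjusted p = 1.1e-06, and 0.293 with estimated correlation). 1 of 17 endoderm genes rose and 13 fell. Together they were lower (adjusted p = 0.000565, and 0.132 with estimated correlation). Sets that passed only at the preset correlation were lower cytosolic ribosomal protein genes (4 rose and 26 fell of 30, adjusted p = 4.35e-08) and integrated stress response genes (2 rose and 10 fell of 16, adjusted p = 0.0146), the lowest at 0.243 with estimated correlation. By edgeR 5676 rose and 5462 fell of 19907 tested. Their number, 11138, became 5202 with the control as reference. CST4, HLA-DOA and NPPB were then lost, at adjusted p between 0.217 and 0.996. Of all 11138 calls 2068 were kept and 1437 turned past the threshold. Of the 13 named genes 7 turned, 6 of them not past it (adjusted p 0.0574 to 0.929).

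NANOS3-ADAR hESC, against the same ADAR reference, expressed NANOS3 at 72.7 CPM. 14 of 17 ectoderm genes rose and 0 fell, with LHX5 (7.39 ± 0.52). Jointly they were higher (adjusted p = 3.78e-05, and 0.0341 with estimated correlation). Highest after NANOS3 were LHX5, FEZF1 (6.69 ± 0.52), DGKB (89.5-fold, 24.5 to 743) and DLK1 (5.90 ± 0.24). Lowest were TBXT (at least 127-fold), MOBP (at least 128-fold), C9orf64 (at least 124-fold), S100A6 (-8.77 ± 0.39) and FOXA2 (463-fold, 158 to 2250). SOX4 was 355 ± 0.416 against 328 ± 18.0 CPM (0.11 ± 0.09, adjusted p = 0.288), and ADAR rose (1.80 ± 0.09) but fell against control (-0.45). For hypoxia and glycolysis genes, 17 of 20 rose and 0 fell, with LDHA (3.50 ± 0.31). As a group they were higher (adjusted p = 3.31e-05, and 0.291 with estimated correlation). Sets that passed only at the preset correlation were lower mitochondrially encoded genes (0 rose and 13 fell of 13, adjusted p = 8.92e-08) and endoderm genes (1 rose and 13 fell of 17, adjusted p = 4.56e-05), the lowest at 0.149 with estimated correlation. By edgeR 5966 rose and 5322 fell of 19907 tested. MOBP and TBXT lost their calls with the control as reference, at adjusted p between 0.200 and 0.418. Of all 11288 calls 3481 were then kept (of 7695 made) and 1625 turned past the threshold. Of the 12 named genes 3 turned, 2 of them not past it (adjusted p 0.373 to 0.537). SOX4 passed with the control as reference (0.27, adjusted p = 0.0167).

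The line with DND1-rAPOBEC1 and NANOS3-ADAR was compared with the mean of the 2 editor lines. With DND1 set aside (see above), the highest were NANOS3, DLK1 (6.18 ± 0.49), NPTX1 (5.67 ± 0.33) and CHGB (5.64 ± 0.56). Lowest were JCHAIN (at least 40.8-fold), REG4 (at least 40.2-fold), NPPB (482-fold, 133 to 3990), SPATA16 (187-fold, 33.2 to 7430) and CEACAM5 (168-fold, 29.8 to 6670). SOX4 was lower (-0.22 ± 0.08, adjusted p = 0.0145), though not per assigned fragment (390.0 and 400.0 CPM against 140 to 307 with an editor alone). ADAR was higher (1.64 ± 0.07), but lower than control (-0.44). Of 13 mitochondrially encoded genes 0 rose and 13 fell. The whole list was lower (adjusted p = 2.93e-09, and 0.411 with estimated correlation). By edgeR 6858 rose and 5853 fell of 19907 tested. Their number, 12711, became 6924 with the control as reference. The threshold was missed, at adjusted p between 0.0550 and 1.00, by SOX4 without the filter or without DND1-rAPOBEC1+NANOS3-ADAR library 1 or 2 and JCHAIN, NPPB and REG4 with the control as reference. With the control as reference 3341 of all 12711 calls were kept and 1752 turned past the threshold. Of the 12 named genes 4 turned, 3 of them not past it (adjusted p 0.444 to 0.575).

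Across hESC, SOX4 rose in DND1-KO and fell in DND1-ADAR relative to its ADAR reference. For the DND1 knockout and fusion 972 genes rose and 783 fell in both, against 931 and 863 expected by chance, and 2401 moved in opposite directions (r = -0.135 across genes). For NANOS3 1415 genes rose and 1647 fell in both, against 1090 and 1100 expected by chance, and 2171 moved in opposite directions (r = -0.056 across genes).

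Whether a knockout acted differently in hPGCLC and hESC was tested as the difference between its 2 effects, with knockout against control CPM given for hPGCLC and then hESC. For DND1-KO the difference was lower for endoderm and mesoderm genes. 0 of 18 endoderm genes had a higher effect in hPGCLC and 8 a lower one (0 and 11 over the list alone). The members together were lower (adjusted p = 2.18e-09, and 0.00108 with estimated correlation). From the mesoderm list, 0 of 18 members were higher and 7 were lower (0 and 8 over the list alone). Tested jointly they were lower (adjusted p = 5.91e-07, and 0.0499 with estimated correlation). Among the largest were the lower AFP (0 against 5.33 and 3.20 against 0.583), DIO3 (8.05 against 10.1 and 1.5 against 0), LEFTY1 (1.12 against 25.9 and 52.4 against 7.12), TCIM (6.23 against 20.6 and 0.420 against 0) and TRDN (0 against 0.907 and 99.5 against 63.7), where AFP was counted in 1 of the 2 control hPGCLC libraries only, and the higher TRPM3 (2.88 against 0 and 3.96 against 12.7), PRKCB (0.990 against 0 and 14.4 against 22.2), IRX6 (336 against 206 and 0 against 0.737) and ALPG (4.61 against 1.18 and 0.315 against 7.80). With 3 counts in place of each 0 the differences stayed at 4.51-fold or more. SOX4, higher in DND1-KO hESC and level in hPGCLC, differed by -0.68 ± 0.17 (adjusted p = 0.00725). For HOX genes, 0 of 26 lay above and 1 below. Camera placed the set lower (adjusted p = 0.000894, and 0.00822 with estimated correlation). The preset correlation alone gave higher G1 and S phase genes (7 above and 0 below of 20, adjusted p = 0.000133) and cytosolic ribosomal protein genes (0 above and 0 below of 30, adjusted p = 0.00653) and lower signalling response genes (2 above and 9 below of 20, adjusted p = 0.00678), amnion and trophoblast genes (0 above and 3 below of 20, adjusted p = 0.0261) and fibroblast genes (0 above and 3 below of 16, adjusted p = 0.0418), the lowest at 0.138 with estimated correlation. By edgeR 904 were above and 914 below of 21843 tested. Their number, 1818, became 666 with only the compared groups, 1164 and 1122 without hESC control library 1 and 2 and 1161 without hESC DND1-KO library 2. At adjusted p between 0.0536 and 1.00, calls were lost by TRDN with RLE normalization or without hPGCLC DND1-KO library 1, IRX6 without the filter, 4 of 10 genes (SOX4 among them) with only the compared groups, IRX6, TCIM and TRDN without hESC DND1-KO library 1, IRX6 and TRDN without hESC DND1-KO library 2 or hESC control library 1 or 2 or hPGCLC control library 2, IRX6, TRDN and TRPM3 without hPGCLC DND1-KO library 2 and AFP, IRX6 and TRDN without hPGCLC control library 1.

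For NANOS3-KO the difference was largest for VGF (9.23 against 1.28 and 2.83 against 39.5), SCG2 (0.786 against 0.107 and 1.5 against 6.97), OLFM3 (15.4 against 0.853 and 0.858 against 1.22), CAMK2N2 (0.528 against 0.107 and 3.27 against 15.3) and MRPL12 (15.8 against 11.7 and 1.33 against 20.8) on the higher side. On the lower, CYS1 (1.77 against 6.64 and 1.81 against 0.0563) is named; 4 further genes had 0 counts in NANOS3-KO hPGCLC against 6 or fewer in control, so their rank rested on the floor. SOX4 gave 0.31 ± 0.17 (adjusted p = 0.212). Among the G1 and S phase genes (20 measured) 14 were above and 1 below. As a set they were higher (adjusted p = 1.02e-07, and 0.0870 with estimated correlation). For cytosolic ribosomal protein genes, 17 of 30 were above and 0 below. The set was higher (adjusted p = 5.84e-07, and 0.713 with estimated correlation). In NANOS3-KO hPGCLC 0 and 1 of the G1 and S phase genes rose and fell, and 0 and 0 of the ribosomal protein genes. By edgeR 2747 were above and 1424 below of 21843 tested. The higher share, 65.9%, became 49.6% with DESeq2 and 49.8% with RLE normalization, with the median of all genes shifted by -0.161 and -0.159 log2. Their number, 4171, became 1527 with only the compared groups. The threshold was missed, at adjusted p between 0.0561 and 0.0916, by SCG2 without hPGCLC NANOS3-KO library 2 and CAMK2N2 without hPGCLC control library 1. NANOS3 passed with DESeq2 (-10.59, adjusted p = 0.000337) and SOX4 passed without hPGCLC NANOS3-KO library 1 (0.49, adjusted p = 0.0408).

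ZNF528 rose and PEG3, LYNX1 and FPGT fell in DND1-KO of both cell types. For DND1-KO, 34 genes rose and 49 fell in both, against 8.45 and 14.8 expected by chance, and 17 moved in opposite directions among 15152 genes tested in both (r = 0.222 across genes), and for NANOS3-KO, 73 genes rose and 74 fell in both, against 40.8 and 65.6 expected by chance, and 71 moved in opposite directions (r = 0.051).

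**Figure D5:**
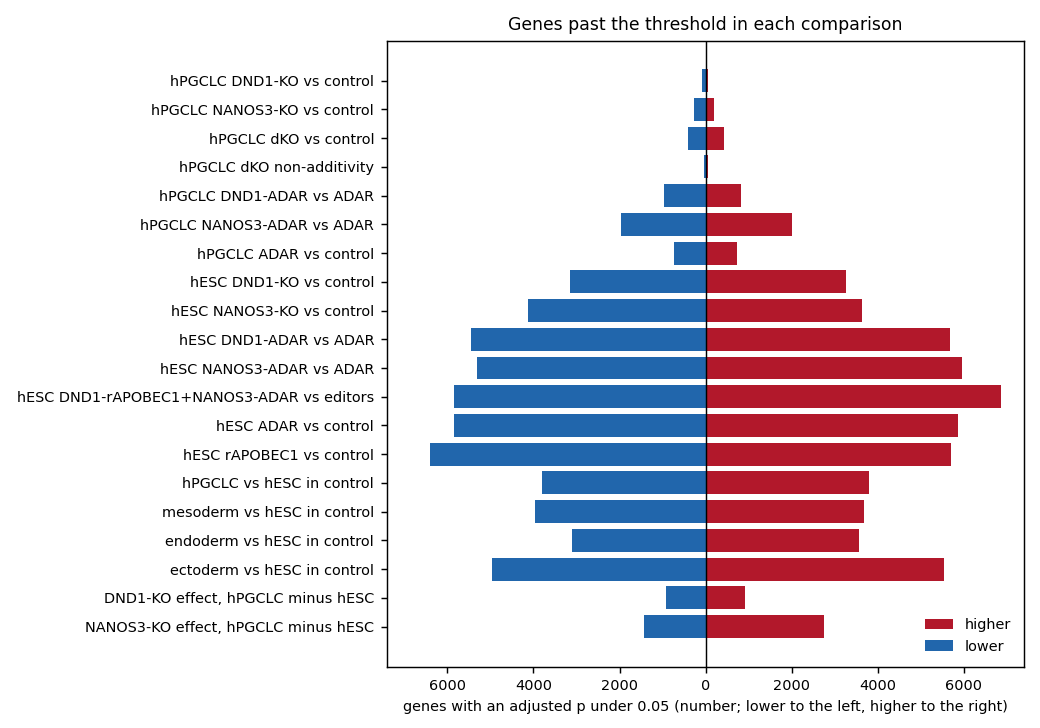
Numbers of genes higher and lower (horizontal axis) past adjusted p = 0.05 in each of the 20 comparisons, groups of 2 libraries. The largest was 12711 for the double fusion hESC and the smallest 98 for the non-additivity of dKO hPGCLC.

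Over the 20 comparisons, 433 list tests gave 122 past the threshold, of which 18 also passed with an estimated correlation.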

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

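Every test of an explanation in this part was chosen after the result was seen. What singled out the values below was a tested difference between hPGCLC and hESC in how a knockout line departed from control.

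For DND1-KO, 1818 genes differed between the cell types. Among them were SOX4 (log2 -0.68), TRPM3 (adjusted p = 0.00699), PRKCB (adjusted p = 0.00332), IRX6 (adjusted p = 0.0358), ALPG (log2 6.50), AFP (adjusted p = 0.00381), DIO3 (adjusted p = 0.000105), LEFTY1 (log2 -7.38), TCIM (adjusted p = 0.00950) and TRDN (adjusted p = 0.0437). SOX4 missed the threshold with only the compared groups (-0.73, adjusted p = 0.0671), and AFP, IRX6, TCIM, TRDN and TRPM3 did in 1 or more alternatives. As sets, with adjusted p in brackets, the lists amnion and trophoblast (0.0261), cytosolic ribosomal protein (0.00653), endoderm (2.18e-09), fibroblast (0.0418), G1 and S phase (0.000133), HOX (0.000894), mesoderm (5.91e-07) and signalling response (0.00678) differed at the preset correlation, and of these only endoderm, HOX and mesoderm with an estimated one.

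For NANOS3-KO, 4171 genes differed, including VGF (log2 6.66), SCG2 (adjusted p = 0.00324), OLFM3 (log2 4.73), CAMK2N2 (adjusted p = 0.00613), MRPL12 (log2 4.39) and CYS1 (adjusted p = 2.92e-05). SCG2 and CAMK2N2 each failed to pass without 1 library. The lists that differed as sets were cytosolic ribosomal protein (5.84e-07) and G1 and S phase (1.02e-07), adjusted p in brackets; with an estimated correlation neither passed (0.713 and 0.0870).

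Genes beside DND1 were lower in the DND1-KO line. ZMAT2 stood at -1.05 ± 0.11 in hESC and -0.83 ± 0.15 in hPGCLC, and HARS2 at -0.86 ± 0.14 in hESC, while IK, on the other side of DND1 (-0.07 ± 0.10 in hESC), did not pass. For DND1 reads counted in a neighbouring gene, only genes overlapping DND1 would be lower, yet 2 genes within 100 kb that did not overlap it were lower in hESC, which excludes this for HARS2 and ZMAT2 and leaves it possible for WDR55. For loss of DND1, dKO should be as low, but ZMAT2 in dKO lay 0.79 ± 0.15 log2 above DND1-KO (adjusted p = 0.00318). That argues against it for ZMAT2 alone. It stays open for HARS2, where dKO lay 0.16 ± 0.22 above DND1-KO, and for WDR55, which was lower still in dKO (by 0.79 ± 0.19, adjusted p = 0.0135). A change at the locus carried by the DND1-KO line remains possible for ZMAT2, whose effects in the 2 cell types differed by 0.24 ± 0.19 (adjusted p = 0.539). Lower genes here were not particular to that line: in NANOS3-KO hESC, where DND1 was not targeted, NDUFA2 (-1.19 ± 0.16), HARS1 (-0.89 ± 0.11), IK (-0.80 ± 0.10) and ZMAT2 (-0.45 ± 0.11) were lower.

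Endoderm genes were higher in DND1-KO hESC. Set against day 5 endoderm, 20 of 20 abundant endoderm genes that were near absent from control hESC were higher, at 0.0832 to 2.27% of their endoderm level (median 0.619%). With carry-over of cells or RNA like the day 5 endoderm libraries, all would share 1 percentage, but 7 genes lay more than 2-fold and 3 SE off it. With fewer pluripotent cells with every lineage raised alike, ectoderm genes would follow, but their median was 0.013%, and that of mesoderm genes 0.13%. Whether a few cells or all cells expressed the endoderm genes could not be tested with these libraries.

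Large changes in hPGCLC, 4-fold or more, were compared with hESC of the same line. For DND1-KO, 41 of 53 genes, such as PEG3 and LYNX1, had moved the same way in hESC, against 15 in NANOS3-KO hESC, so a difference the line already carried in hESC may account for many of them. For NANOS3-KO, 18 of 55 did so, against 16 in DND1-KO hESC, so most had no such counterpart. If loss of DND1 caused the DND1-KO changes, they would persist in dKO, by label also without DND1. Of 53, 35, such as LYNX1, lay back towards control. They differed from DND1-KO, not control, and NANOS3-KO alone did not move them that way. DND1 was not measurable, so this argues against that cause for the 35 only, without excluding it. Of the NANOS3-KO changes 7 of 55 lay back, which does not settle loss of NANOS3. The labels do not say from which line dKO was made.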

How the results depend on the processing

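The recounts of overlaps, the split of the controls and the fits without the hPGCLC ADAR libraries, without the hESC editor-only libraries and without the mitochondrially encoded genes were chosen after the results were seen. Numbers of genes past the threshold moved as follows. Changes were in hPGCLC DND1-KO from 126 to 484 without filter, 28 with only the compared groups, 259 with DESeq2 and 55 to 1443 leaving out 1 library, hPGCLC NANOS3-KO from 467 to 1167 without filter, 2 with only the compared groups, 295 without the hPGCLC ADAR libraries, 865 with DESeq2 and 91 to 1732 leaving out 1 library and hPGCLC dKO from 838 to 1428 without filter, 34 with only the compared groups and 126 to 1737 leaving out 1 library. Further, in hPGCLC dKO non-additivity from 98 to 467 without filter, 26 with only the compared groups, 246 with DESeq2 and 30 to 848 leaving out 1 library, hPGCLC DND1-ADAR from 1776 to 818 against the control, 4616 with only the compared groups and 435 to 967 leaving out 1 library and hPGCLC NANOS3-ADAR from 3979 to 1874 against the control and 1726 to 2689 leaving out 1 library. Beyond that, in hPGCLC ADAR from 1462 to 316 with only the compared groups and 434 to 2214 leaving out 1 library, hESC DND1-ADAR from 11138 to 5202 against the control and hESC double fusion from 12711 to 6924 against the control. Likewise in hPGCLC vs hESC from 7584 to 4896 to 6849 leaving out 1 library, mesoderm vs hESC from 7623 to 11738 with only the compared groups and 4902 to 4929 leaving out 1 library and endoderm vs hESC from 6677 to 11334 with only the compared groups and 3716 to 3993 leaving out 1 library. Then in DND1-KO difference from 1818 to 666 with only the compared groups and 1122 to 2296 leaving out 1 library and NANOS3-KO difference from 4171 to 1527 with only the compared groups. Of 122 list tests past the threshold, 18 passed with an estimated correlation. Genes shared in the same direction became 76 without filter and 28 with DESeq2 for hPGCLC DND1-KO and hPGCLC DND1-ADAR, 43 without filter and 20 with DESeq2 and 17 with controls split 1 of 2 ways (beside 526 opposite) for hPGCLC DND1-KO and hPGCLC NANOS3-KO, 118 without filter and 53 with DESeq2 and 50 with controls split 1 of 2 ways (beside 373 opposite) for hPGCLC DND1-KO and hPGCLC dKO, 517 without filter and 401 with DESeq2 for hPGCLC NANOS3-KO and hPGCLC NANOS3-ADAR and 403 without filter and 278 with DESeq2 for hPGCLC NANOS3-KO and hPGCLC dKO. Against the control instead of the editor line the direction turned, in log2, for hESC DND1-ADAR ADAR -0.22, ADRA2A -2.21, ANKRD1 5.41, CST1 2.35, KAT6B -0.03, PCDHAC2 -0.07, TNRC6A -0.04; for hESC double fusion ADAR -0.44, CEACAM5 2.18, SOX4 0.07, SPATA16 2.18; for hESC NANOS3-ADAR ADAR -0.45, FOXA2 1.25, LDHA -0.33; for hPGCLC DND1-ADAR LEFTY1 -0.85, LEFTY2 -1.98, PON3 4.24, TRIM4 -0.22, VTCN1 0.17, WNT6 2.19; for hPGCLC NANOS3-ADAR LEFTY2 -2.04, TRIM4 -0.18, WNT6 2.53. Of these only ADRA2A, WNT6 in hPGCLC NANOS3-ADAR and ADAR in the hESC double fusion and hESC NANOS3-ADAR passed. The median of all genes in the NANOS3-KO difference shifted by -0.159 with RLE, -0.129 without filter, -0.159 without the hESC editor-only libraries and -0.161 with DESeq2, and the share of higher genes from 65.9% to 49.8, 52.6, 50.3 and 49.6%. Without the editor-only libraries the DND1-KO difference kept its number (1803) but its higher share fell by 12.5 points. With a replicate block, DND1-KO hPGCLC gave 136 genes, NANOS3-KO 538 and dKO 862, and 5 named genes no longer passed. Over 28 pairs of groups in hESC, 21 in hPGCLC and 10 in controls, correlations of replicate differences had medians of -0.007, 0.002 and -0.03 and maxima of 0.161, 0.172 and 0.076, too low to show pairing. A library left alone in its group was assumed to vary like the other groups. The cause of these shifts was not tested.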

Other observations

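The genes in this part were chosen after the results were seen. PEG3, an imprinted zinc finger gene with 51% of its exon bases shared with another gene, was low in lines that had different targets: DND1-KO hPGCLC (at least 52.1-fold), NANOS3-KO (-3.20 ± 0.54), dKO (245-fold, 43.4 to 9740) and ADAR hPGCLC (at least 70.4-fold), and DND1-KO (at least 384-fold), ADAR (-5.57 ± 0.24) and rAPOBEC1 (-4.96 ± 0.27) hESC. TRIM61 was low in DND1-KO, NANOS3-KO, dKO and ADAR hPGCLC, and CHCHD2 in NANOS3-KO and dKO hPGCLC, NANOS3-KO hESC and also DND1-ADAR hPGCLC against ADAR (-5.86 ± 0.34), where NANOS3 was not targeted. LEFTY1 and LEFTY2 fell in DND1-KO, dKO and ADAR hPGCLC against control. Not all of these calls held: with only the compared groups PEG3 and TRIM61 in NANOS3-KO and TRIM61 in dKO were lost, and leaving out 1 library lost PEG3 in NANOS3-KO and LEFTY1 and LEFTY2 in DND1-KO and dKO hPGCLC.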
